A study of Mus musculus with 6 samples.

How the data were processed

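The RNA selection step is not given in the sources used here; per the labels' protocols, total RNA was extracted with a Qiagen RNeasy mini kit and libraries were made with a NEBNext Ultra II RNA kit. Whether the counting used strand is not given, so reads of a gene and of an antisense or overlapping gene cannot be told apart. The submitters' processing notes name bcl2fastq, FastQC 0.11.9, Bowtie2 with the version 2.7.3a, and the genome build GRCh38. The deposited files hold mouse gene identifiers: of 54532 genes listed per library, 54495 are in the GENCODE mouse annotation of GRCm38, and 53585 of those have the same start and end there, or 98.33%. Coordinates are therefore given as the files state them, on GRCm38. The aligner settings and the counting program are not given in the sources used here.

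The deposited values are raw read counts per gene, whole numbers with no normalization, in 1 file per library. The 6 libraries hold 129715355 counts together. Each library was assigned to its group and replicate number from its label. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Libraries were compared in pairs by a chi-square statistic per gene, which ranged from 5.26 to 14.7 within groups and from 5.55 to 19.1 between groups, so that no pair differed by as little as sampling noise and each library was counted once.

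Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed by filterByExpr with the group as factor and its default minimum count of 10, which left 14129 genes. Library sizes were scaled by the trimmed mean of M-values (TMM), and the groups were compared by the quasi-likelihood F-test (glmQLFit and glmQLFTest without robust estimation), as 2'-fucosyllactose minus control, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were taken from the fold change and its F statistic. Counts scaled to a common library total (CPM), with TMM factors, are given for tested genes, and CPM of the library total for markers, including those below the filter.

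For gene groups, 37 lists were fixed before the data were examined. Each list with at least 5 tested members was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Member counts are given over all genes tested and adjusted over the list alone. Adjustment over a list alone does not account for the number of lists, so some such calls can arise by chance. How many would do so was not estimated, which matters most where 1 member of a list passed. Another 4 lists were written after the data were seen and serve only the closing observations. Named genes followed a rule fixed beforehand: the 10 largest changes in each direction among genes past the threshold, and, where fewer than 20 passed, the 10 genes with the smallest p in each direction with a mean of at least 1 CPM, as values that did not pass; 10 genes of EGF receptor signalling; the 2 most abundant members of each list of another cell type; and the 2 members with the smallest p of each list whose test passed. Genes without a proper name were skipped. Members that passed adjusted over a list alone, or over all genes by DESeq2, are named as well where a list had few of them, chosen after their values were seen. The values of 1 gene that the rule names are not reported here.

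The total count, genes detected, share of mitochondrial counts and share of the 50 highest genes were compared by an exact two-sided permutation test, which with 3 against 3 libraries cannot give a p below 0.1. GC content and length of the reference transcripts were available for 99.9% of the tested genes. A count of 0 was read as allowing up to 3 counts of the total; such floors cover counting error only. With the 6 libraries together, the floor is 0.0231 CPM.

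The edgeR test was checked on simulated counts with the means, dispersions and library sizes of these libraries. Of 200 genes changed by known amounts, it recovered 34% at a fold of 1.25, 60% at 1.5, 70% at 2 and 86% at 3, among 13938 genes tested, with 13 of 138 calls in unchanged genes. With no gene changed, 0 of 13954 genes and 0 lists passed. Simulated genes vary independently of each other, which real genes do not, so the simulation says little about the calibration of the list test.

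Alternatives fixed before the data were examined were other scalings, no filter, a stricter filter of 1 CPM in 3 libraries, a replicate block, DESeq2 1.42.0, limma-voom, robust estimation, a minimum fold of 1.5, and each library left out in turn. Thinning all libraries to the smallest total, removing each library's trend with GC content and length, and leaving out both libraries that stood apart on the principal components were added after the data were seen.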

Results

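RNA was sequenced from YAMC cells, a conditionally immortalised line described in the labels as young adult mouse colonic epithelium, which carries a temperature-sensitive SV40 large T antigen under an interferon-gamma-inducible promoter and was grown at 33 °C with interferon-gamma. In 3 libraries the cells had received 2'-fucosyllactose (2'-FL), a fucosylated oligosaccharide of human milk, at 20 µg/ml for 6 h, and 3 control libraries came from untreated cells. The sample titles give 6 h for the 2'-FL libraries and no time for the controls, so time in culture may differ between groups. Total counts were 23321988, 25251187 and 19978583 for 2'-FL replicates 1 to 3 and 19991723, 21067476 and 20104398 for control replicates 1 to 3. The files list between 19955 and 20828 genes with at least 1 count per library. Total counts averaged 22850586 ± 2667724 with 2'-FL and 20387866 ± 591250 in controls (SD, n = 3 each, exact two-sided permutation p = 0.4, adjusted p = 0.5). Mitochondrial genes took 0.495 ± 0.126% of counts with 2'-FL and 0.480 ± 0.0379% in controls (SD, n = 3 each, exact two-sided permutation p = 0.9). These counts were uneven between genes, with 295 for mt-Co2, 341 for mt-Co3 and 299 for mt-Atp6 over the 6 libraries, against 298450 for mt-Co1. The share may therefore miss mitochondrial reads, which was not tested. The 50 highest genes took 9.94 ± 0.337% and 9.58 ± 0.138% (SD, n = 3 each, exact two-sided permutation p = 0.2, where 0.1 is the smallest p this design allows).

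The first question was which transcripts differed after 6 h of 2'-FL. The genes with the smallest p that were lower with 2'-FL were Ifi203, Ly6a, Slfn2, Ccl5, Ifit3b, Mndal, Oas2, Etv4, Ifi206 and Rsad2, most of them known as interferon-inducible. Those that were higher were Acta2, Limch1, Map6, Sytl1, Mcam, Dapk1, Eng, Tpm2, Qpctl and Myl9, of which Acta2, Tpm2 and Myl9 encode actin, tropomyosin and myosin light chain of contractile filaments. By edgeR none of these 20 passed over all genes: its quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 14129 genes, with 1116 genes at an unadjusted p under 0.05, where 706 would be expected with no effect. The DESeq2 Wald test called 32 genes, 8 higher and 24 lower, and limma-voom called 0. DESeq2's calls include 15 of the 20 named genes, all but Rsad2, Acta2, Dapk1, Eng and Qpctl. By edgeR, 12 of the 20 passed without 2'-FL replicate 1, 9 without control replicate 2, 5 with robust estimation and 20 without a filter on low counts. Without a filter, the fitted prior degrees of freedom were infinite, so that a gene's own spread no longer counted. Calls without a filter, here and below, therefore carry little weight.

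Ifi203, a member of the interferon-inducible p200 family on chromosome 1 (173920407 to 173942672, minus strand, GRCm38), averaged 91.1 ± 2.38 CPM with 2'-FL and 128 ± 11.04 CPM in controls (SD, n = 3 each), a log2 fold change of -0.49 ± 0.07 (SE) with an adjusted p of 0.0914 in edgeR. Its annotated span overlaps that of Mndal on the same strand, so reads of the pair are uncertain. Ly6a, the surface antigen Sca-1, had a log2 fold change of -0.45 ± 0.07 (SE), Slfn2 of -0.45 ± 0.08 (SE) and the chemokine Ccl5 of -0.68 ± 0.12 (SE), each at the same edgeR adjusted p of 0.0914. By the DESeq2 Wald test the adjusted p was 3.97e-05 for Ifi203, 6.11e-05 for Ly6a, 0.00118 for Slfn2 and 7.02e-05 for Ccl5. In the other direction, Acta2, smooth muscle actin on chromosome 19 (34241090 to 34255336, minus strand), averaged 339 ± 124 CPM with 2'-FL and 168 ± 31.1 CPM in controls (SD, n = 3 each), a log2 fold change of 1.01 ± 0.20 (SE) with an edgeR adjusted p of 0.197. Limch1, Map6 and Sytl1 had log2 fold changes of 0.43 ± 0.09, 0.34 ± 0.07 and 0.35 ± 0.07 (SE), and DESeq2 adjusted p of 0.0230, 0.0241 and 0.0322. The melanoma cell adhesion molecule Mcam stood at 539 ± 57.0 CPM against 419 ± 18.5 CPM (SD, n = 3 each), and endoglin, Eng, at 14.5 ± 0.551 CPM against 9.74 ± 1.29 CPM (SD, n = 3 each).

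The series title names transactivation of the EGF receptor, so the transcripts of its family were examined next. Transcript levels at 6 h do not measure activation of the receptor protein, so they speak neither for nor against it. The receptor transcript Egfr was abundant in both groups, at 272 ± 4.92 CPM with 2'-FL and 285 ± 20.97 CPM in controls (SD, n = 3 each), a log2 fold change of -0.06 ± 0.07 (SE) that did not pass the test. Erbb2 and Erbb3, its co-receptors, had log2 fold changes of 0.03 ± 0.08 and 0.06 ± 0.16 (SE). Among the ligands, Ereg (-0.03 ± 0.08), Hbegf (-0.03 ± 0.15), Areg (-0.11 ± 0.34) and Tgfa (-0.25 ± 0.22) had log2 fold changes within about 1 standard error of 0. The ligand betacellulin, Btc, fell from 32.4 ± 1.71 to 26.0 ± 1.14 CPM (SD, n = 3 each) when p-values were adjusted over the list alone (edgeR adjusted p = 0.0379), and did not pass over all genes (adjusted p = 0.319). Adam10 and Adam17, sheddases that release ligands, had log2 fold changes of 0.11 ± 0.07 and 0.04 ± 0.06 (SE). Of 21 tested members, 0 passed over all genes by edgeR, the DESeq2 Wald test or limma-voom, and 1 adjusted over the list alone by edgeR. That count was 0 without 2'-FL replicate 1 or 3, without control replicate 1 or 3, by the DESeq2 Wald test, with GC and length trends removed and without both libraries that stood apart on the principal components, and it was 2 without control replicate 2 and without a filter on low counts. The list as a set did not pass camera (adjusted p = 0.311).

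**Figure D1:**
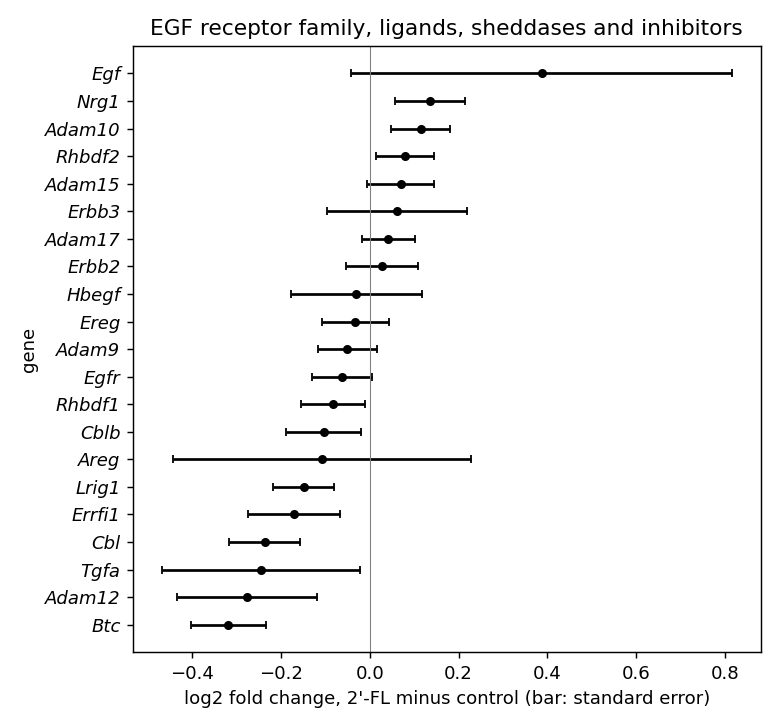
Log2 fold changes (2'-FL minus control, horizontal axis) of the 21 tested genes of the EGF receptor family list, with standard errors as bars (n = 3 libraries per group). Egfr lies at -0.06 and Btc at -0.32.

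Among genes induced by ERK signalling downstream of growth factor receptors, 24 of 32 tested members had log2 fold changes below 0, with a median of -0.08. Mean levels of the list, on the log2 scale around the mean of all libraries, overlapped between groups (exact two-sided permutation p = 0.5). They were 0.08, -0.22 and -0.04 in 2'-FL replicates 1 to 3 and -0.07, 0.07 and 0.18 in control replicates 1 to 3. The transcription factor Etv4 fell when adjusted over the list alone, with a log2 fold change of -0.47 ± 0.09 (SE, edgeR adjusted p = 0.0042), as the 1 member of the list that passed with all libraries. Without 2'-FL replicate 1 that count was 4, with Dusp4, Egr1 and Etv5 added, and it was 2, Dusp4 and Etv4, without control replicate 2 and without a filter on low counts. Over all genes 0 members passed by edgeR and limma-voom, and 1 by the DESeq2 Wald test, Etv4 (adjusted p = 0.0218). Its relative Etv5 had a value of -0.26 ± 0.08 (SE) that did not pass with all libraries. Phosphatases of the list went both ways and did not pass with all libraries and the filter, with Dusp4 at -0.36 ± 0.12 and Dusp6 at -0.19 ± 0.08, and Dusp1 at 0.20 ± 0.08 and Dusp5 at 0.15 ± 0.08 (SE); these genes were chosen after their values were seen. The set did not pass camera (adjusted p = 0.128). Among 18 tested targets of FOXO factors, Txnip, the thioredoxin-interacting protein, fell when adjusted over the list alone, with a log2 fold change of -0.29 ± 0.07 (SE, edgeR adjusted p = 0.0261), against 0 over all genes by edgeR, the DESeq2 Wald test or limma-voom, and the list did not pass camera (adjusted p = 0.101). The Txnip call was lost without 2'-FL replicate 2 or 3, without control replicate 1 or 2 and without both libraries that stood apart on the principal components, and Irs2 passed beside it without 2'-FL replicate 1, without a filter and with GC and length trends removed.

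Interferon-stimulated genes had the smallest camera p of the 33 lists tested, and their levels were lower with 2'-FL. Of 43 tested members, 41 had lower mean levels with 2'-FL, and 27 fell when adjusted over the list alone, against 0 over all genes by edgeR. The DESeq2 Wald test called 5 members over all genes, each lower, namely Ifit3b, Ifit3, Mx1, Cmpk2 and Irf7, and limma-voom called 0. The antiviral genes Ifit3b and Rsad2 had log2 fold changes of -0.44 ± 0.08 and -0.62 ± 0.13 (SE), with Rsad2 at 161 ± 17.9 CPM with 2'-FL and 246 ± 54.0 CPM in controls (SD, n = 3 each). Mx1 and Cmpk2 had -1.01 ± 0.22 and -0.47 ± 0.11 (SE), and the median of the list was -0.22. The list passed camera with the preset correlation (adjusted p = 7.62e-16) and did not with an estimated one (adjusted p = 0.702 with an estimated correlation). The estimate was 0.39 against the preset 0.01, so the camera p with the preset correlation may be far too small. Mean levels in the 3 2'-FL libraries, from -0.15 to -0.11 on the log2 scale around the mean of all libraries, lay below those of the controls, at 0.21, -0.02 and 0.18, with control replicate 2 nearest to them. The number of members that fell, adjusted over the list alone, was 11 without 2'-FL replicate 3, 11 without control replicate 1 and 7 without control replicate 3. Reads of Ifit3 and Ifit3b, near-identical copies, may have been split by the counting. Antigen presentation genes, also inducible by interferon, had a median of -0.05 and 0 of 22 members passing adjusted over the list alone or over all genes.

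Inflammatory NF-kB targets included several lower chemokines, with 21 of 30 tested members lower and 9 higher. The chemokines Ccl5, Ccl7, Ccl2 and Cxcl5, the cytokine Il6 and the adhesion molecule Vcam1 fell when adjusted over the list alone, making 6 of 30 tested members, against 0 over all genes by edgeR. Over all genes the DESeq2 Wald test called 2 of the list, Ccl5 and Ccl7, both lower, and limma-voom called 0. Ccl7 stood at 76.2 ± 11.1 CPM with 2'-FL and 105 ± 8.17 CPM in controls (SD, n = 3 each), and Il6 had a log2 fold change of -0.83 ± 0.27 (SE). The list passed camera (adjusted p = 0.0084; adjusted p = 0.702 with an estimated correlation). Its median was -0.09, and its call was lost without 2'-FL replicate 3 (median -0.067, adjusted p = 0.0799) and without control replicate 3 (median -0.051, adjusted p = 0.0806). Adjusted over the list alone, 2 members, Ccl5 and Ccl7, passed without 2'-FL replicate 2 or 3, without control replicate 2 or 3 and with GC and length trends removed, 3 passed with upper-quartile scaling or robust estimation, and 9 passed without a filter, 2 of them higher, and without 2'-FL replicate 1, 1 of them higher.

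Contractile genes listed as markers of smooth muscle were higher with 2'-FL in all 8 tested members. Acta2, Myl9 and the actin-binding calponin Cnn1, 3 of the 8, rose when adjusted over the list alone, against 0 over all genes by edgeR and limma-voom and 1, Myl9, by the DESeq2 Wald test (adjusted p = 0.0485). Myl9 and Cnn1 had log2 fold changes of 0.76 ± 0.17 and 0.74 ± 0.24 (SE). Cald1, the most abundant member, had 0.17 ± 0.07 (SE). The list passed camera (adjusted p = 2.86e-05; adjusted p = 0.455 with an estimated correlation), and its median was 0.64. Adjusted over the list alone, 6 members passed without control replicate 1 and without a filter, with Actg2, Cald1 and Tagln added, 5 without 2'-FL replicate 1, with Actg2 and Cald1 added, and 4 by DESeq2 and with GC and length trends removed, with Cald1 added. The Cnn1 call was lost without 2'-FL replicate 2, without control replicate 3 and without both libraries that stood apart on the principal components, and the Acta2 call with robust estimation. Acta2 was highest in 2'-FL replicate 2, at 454 CPM, the library farthest from the others on the first principal component (28.0% of variance), and lowest in control replicate 3, at 132 CPM. Fibroblast markers, measured beside them, had a median of 0.04 over 17 members, with 1, Thy1, higher adjusted over the list alone, and did not pass camera (adjusted p = 0.298). Without 2'-FL replicate 1 and without a filter 4 members passed, 3 of them higher, and 2 passed by DESeq2. The Thy1 call was lost without any 1 library other than 2'-FL replicate 1, with the stricter filter, by limma-voom, when thinned and without both libraries that stood apart on the principal components.

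A further 5 lists passed camera upward with 0 members passing adjusted over the list alone, or over all genes by edgeR, the DESeq2 Wald test or limma-voom. Targets of p53 had a median log2 fold change of 0.10, with Perp at 0.20 ± 0.08 and the cell cycle inhibitor Cdkn1a at 0.14 ± 0.06 (SE; adjusted p = 0.0010). Antioxidant genes had 0.09, with Nqo1 at 0.28 ± 0.09 and Hmox1 at 0.20 ± 0.07 (SE; adjusted p = 0.0041). Cholesterol synthesis genes had 0.14, with Nsdhl at 0.32 ± 0.13 (SE; adjusted p = 0.0010). Amino acid response genes had 0.12, with Trib3 at 0.35 ± 0.14 and Aldh1l2 at 0.36 ± 0.15 (SE; adjusted p = 0.0041), and mitosis genes 0.07, with Cdc25c at 0.22 ± 0.10 and Cdc20 at 0.16 ± 0.07 (SE; adjusted p = 0.0466). For each of the 5, adjusted p = 0.702 with an estimated correlation. The estimates were 0.69 for cholesterol, 0.55 for amino acid, 0.52 for mitosis, 0.11 for p53 and 0.10 for antioxidant genes. All lie above the preset 0.01, so the camera p with the preset correlation may be too small. Without 2'-FL replicate 2, the cholesterol, amino acid, mitosis and antioxidant calls were lost (adjusted p = 0.330, 0.630, 0.743 and 0.0782) and their medians were 0.042, 0.031, 0.027 and 0.031, with the Nsdhl log2 fold change at 0.19, the Trib3 log2 fold change at 0.21, the Aldh1l2 log2 fold change at 0.20, the Cdc25c log2 fold change at 0.11, the Cdc20 log2 fold change at 0.069 and the Hmox1 log2 fold change at 0.13. Without control replicate 3, the cholesterol, amino acid and mitosis calls were lost (medians 0.093, 0.090 and 0.048, adjusted p = 0.148, 0.0612 and 0.273), and without control replicate 2 the amino acid and mitosis calls (medians 0.11 and 0.048, adjusted p = 0.206 and 0.417). Of the 33 lists tested, 8 passed camera with the preset correlation, 6 higher and 2 lower, and 0 with an estimated correlation or by fry.

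**Figure D2:**
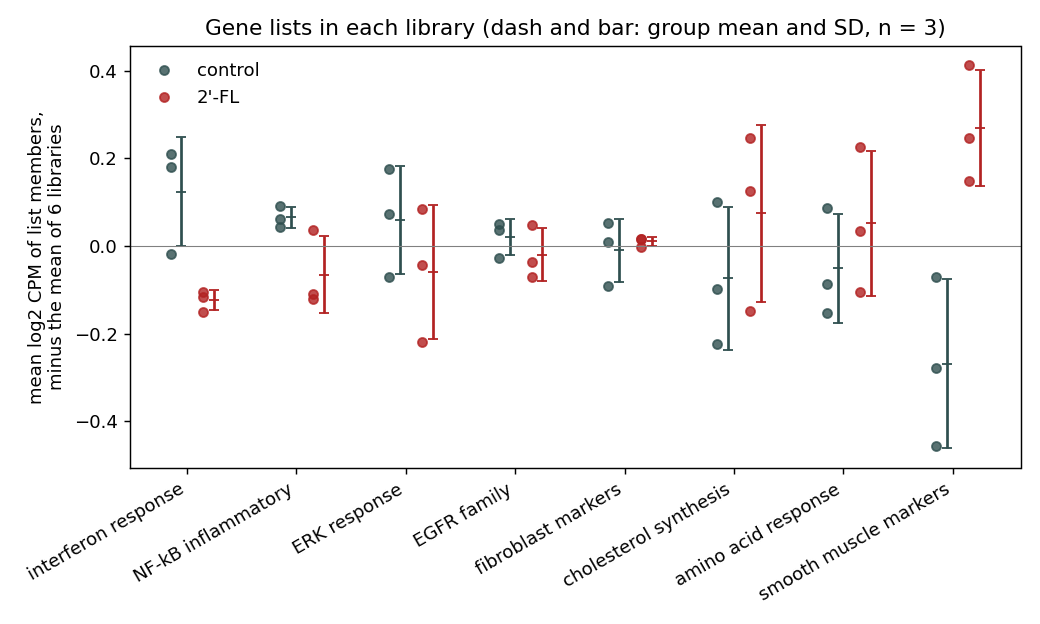
Mean log2 CPM of the tested members of 8 lists in each library, minus the mean of the 6 libraries (vertical axis), with points for libraries and dash and bar for the group mean and SD (n = 3 each). Interferon response scores are -0.12 on average with 2'-FL and 0.12 in controls, while cholesterol synthesis and amino acid response scores overlap between groups.

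Markers of cell types showed abundant collagen and keratin transcripts and few colonocyte transcripts. Collagens Col1a1 and Col3a1 were the most abundant fibroblast markers, at 3768 ± 504 and 2882 ± 199 CPM with 2'-FL and 3342 ± 191 and 2509 ± 54.3 CPM in controls (SD, n = 3 each). The simple epithelial keratins Krt8, Krt18 and Krt19 averaged 307 ± 47.3, 271 ± 15.9 and 392 ± 48.9 CPM over all libraries (SD, n = 6). Of 25 colonocyte genes, 21 averaged under 1 CPM, as did 18 of 20 goblet cell genes, so these lists had 4 and 3 tested members and were not tested as sets. The epithelial adhesion genes Cdh1 and Epcam averaged 0.651 ± 0.256 and 0.337 ± 0.196 CPM (SD, n = 6). Other junction genes were abundant: of 30 in that list, 15 averaged over 10 CPM and 13 under 1 CPM, with F11r, Jup and Cldn15, chosen after their values were seen, at 491 ± 23.8, 235 ± 15.9 and 71.3 ± 5.90 CPM (SD, n = 6). Pkp2, a desmosomal plakophilin of that list, rose when adjusted over the list alone, with a log2 fold change of 0.34 ± 0.08 (SE, edgeR adjusted p = 0.0116), as 1 of 20 tested members, against 0 over all genes by edgeR, the DESeq2 Wald test or limma-voom, and that call was lost without 2'-FL replicate 2 or 3, without control replicate 2 and without both libraries that stood apart. The junction list did not pass camera (adjusted p = 0.573), with a median of 0.02 and a mean of -0.04. The intestinal transcription factor Cdx2 and the colonic anion exchanger Slc26a3 had 0 counts in the 6 libraries, which allows up to 0.0231 CPM. Leukocyte markers were low, with 18 of 20 under 1 CPM; Cd68 and Csf1r were the highest and had log2 fold changes of 0.15 ± 0.12 and -0.52 ± 0.43 (SE). The endothelial marker Eng rose when adjusted over the list alone, with a log2 fold change of 0.57 ± 0.13 (SE, edgeR adjusted p = 0.0027), as 1 of 6 tested members, against 0 over all genes by edgeR, the DESeq2 Wald test or limma-voom; that list did not pass camera (adjusted p = 0.573). The highest endothelial markers, Esam and Flt1, had -0.05 ± 0.08 and -0.25 ± 0.16 (SE), and the highest tuft and enteroendocrine markers, Dclk1 and Trpm5, had -0.01 ± 0.09 and -0.20 ± 0.28 (SE); these 4 did not pass.

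**Figure D3:**
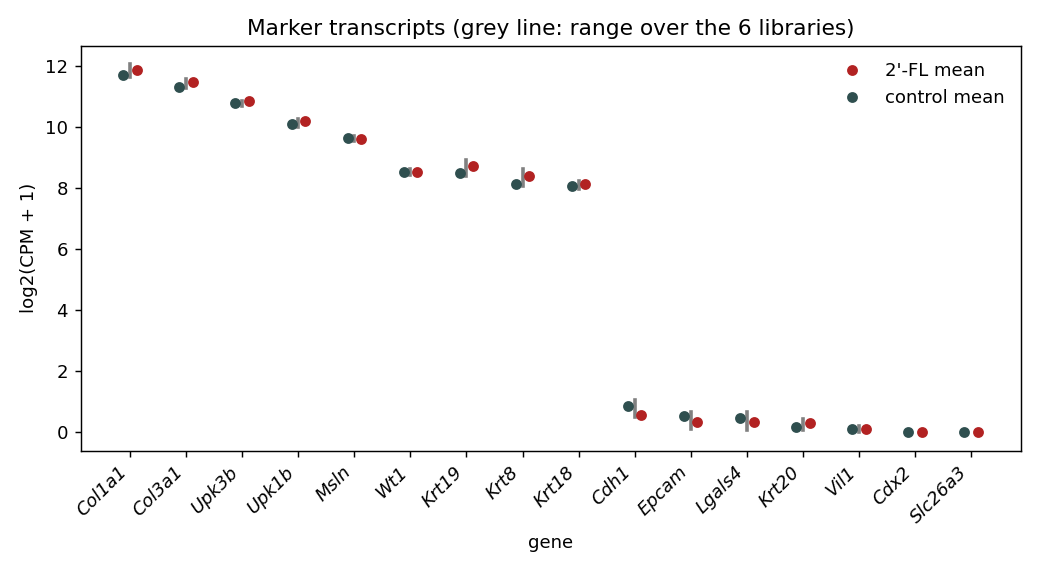
Levels of 16 marker genes as log2(CPM + 1) on the vertical axis, with points for the group means and a grey line for the range over the 6 libraries. Col1a1 and Upk3b lie near the top, and Cdx2 and Slc26a3 lie at 0 in every library.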

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

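Thinning, the removal of GC and length trends and of both libraries that stood apart, and the counts of interferon genes under other settings were chosen after the data were seen. The number of genes past the threshold was 0 by edgeR's quasi-likelihood test and stayed 0 under both other scalings, the stricter filter, limma-voom, a minimum fold of 1.5 and the 3 settings added later. It was 32 with DESeq2, 5 with robust estimation, and between 0 and 28 with 1 library left out (21 without 2'-FL replicate 1, 28 without control replicate 2, otherwise 0); the cause was not tested. Without a filter it was 158. The fitted prior degrees of freedom were then infinite, against 10.6 with the filter, so that a gene's own spread no longer counted. What made them infinite was not tested. With a replicate block 1 gene, Ccl5, passed (adjusted p = 0.0393 by edgeR), and the Btc call over its list alone and the mitosis list's call were lost; adjusted over their lists alone, Dusp4 passed, Thy1 and Txnip no longer did, and 2 inflammatory and 20 interferon genes passed; deviations of libraries with the same number correlated at -0.12, -0.07 and -0.05, so the numbers did not pair the samples, and 0 of 3 2'-FL libraries matched best with their own number. Lists past camera numbered 8, but 0 with an estimated correlation and 0 by fry, and 5 to 13 with 1 library left out (5 without control replicate 3, 13 without 2'-FL replicate 1). The mitosis list's call was also lost without a filter (adjusted p = 0.0634), and without both libraries that stood apart the calls of the mitosis (adjusted p = 0.0511) and antioxidant lists (adjusted p = 0.143) were lost. Interferon genes that fell adjusted over the list alone numbered 27, 10 without both libraries that stood apart and 7 to 32 with 1 library left out. The EGF receptor family had 0 members past over all genes under every alternative run. Signs of small changes turned: the Ereg log2 fold change was 0.022 with trends removed and 0.0059 without both libraries apart, the Hbegf log2 fold change 0.12 without both, and the Dclk1 log2 fold change 0.00079 without a filter, 0.015 when thinned and 0.051 with trends removed; the cause was not tested. With 1 library left out, Erbb2 ranged from -0.035 to 0.11, Erbb3 from -0.094 to 0.22, Areg from -0.33 to 0.13, Ereg from -0.10 to 0.044, Hbegf from -0.20 to 0.11, Esam from -0.098 to 0.013 and Dclk1 from -0.047 to 0.021. Others moved without turning: Egfr from -0.11 to -0.0040, Tgfa from -0.31 to -0.13, Adam10 from 0.068 to 0.15, Adam17 from 0.031 to 0.063, Cd68 from 0.036 to 0.31, Csf1r from -0.93 to -0.26, Flt1 from -0.42 to -0.11, Trpm5 from -0.41 to -0.046, Col1a1 from 0.062 to 0.25 and Cald1 from 0.11 to 0.22. List medians reached 0.28 for cholesterol, 0.20 for amino acid and 0.11 for mitosis genes and -0.14 for inflammatory genes. No scaling moved the median of all genes by over 0.1. At this depth, genes under 1 CPM rest on few counts.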

Other observations

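The mesothelial, type I interferon, interferon-gamma, and serum response factor and actin lists, the tests on marker levels, the genome build, kinds of interferon genes and smooth muscle transcripts, the splits for the interferon and smooth muscle lists, and the thinning and trend corrections were chosen after the data were seen. Transcripts typical of mesothelial cells, the lining of body cavities, were abundant in every library. Upk3b, Upk1b, mesothelin (Msln) and Wt1 averaged 1790 ± 79.1, 1127 ± 72.5, 787 ± 31.2 and 366 ± 17.8 CPM (SD, n = 6), and Upk3b ranked 18 among all genes. Of 14 genes in the list, 11 were over 10 CPM and 2 under 1 CPM; 0 of the 14 are in another list. Fn1, Col1a1 and Sparc were among the 4 highest transcripts, at 5212, 3547 and 3423 CPM. The mesothelial list had a median log2 fold change of 0.01 and a mean of -0.06 over 12 tested members. Muc16 and Pkhd1l1, 2 of the 12, fell when adjusted over the list alone, with edgeR log2 fold changes of -0.59 ± 0.15 and -0.42 ± 0.11 (SE; adjusted p = 0.0121 and 0.0125), against 0 over all genes by edgeR, the DESeq2 Wald test or limma-voom. Without control replicate 1 Muc16 had -0.36, and without 2'-FL replicate 2 Pkhd1l1 had -0.28. Over the list alone, the Pkhd1l1 call was lost without control replicate 3 (adjusted p = 0.0901), the Muc16 call by DESeq2 (adjusted p = 0.131), and both without both libraries that stood apart (adjusted p = 0.0728 each) and with robust estimation (adjusted p = 0.239 for Muc16 and 0.147 for Pkhd1l1).

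This profile stands beside the near absence of colonocyte transcripts. A minor share of other cells in a colonic epithelial culture would leave the epithelial transcripts abundant. The median of Epcam, Cdh1, Cldn7, Vil1, Cdx2, Lgals4 and Krt20 was at most 0.348 CPM in any library. These 7 genes were chosen after the data were seen and each averaged under 1 CPM, so their low median is no test. In the lists fixed beforehand, 21 of 25 colonocyte genes averaged under 1 CPM and 4, all keratins, over 10 CPM. Of 30 junction genes, 13 averaged under 1 CPM and 15 over 10 CPM. The median was 0.0656 CPM over the colonocyte list and 0.0108 CPM over the goblet cell list, with 18 of 20 goblet cell genes under 1 CPM. These levels argue against cells with a colonocyte or goblet cell profile as the main part of the culture. The keratins and the abundant junction genes go the other way, so epithelial cells without that profile stay open. A human build, as the submitters' processing notes name, is argued against by the coordinates, since 98.33% of the shared genes have the mouse GRCm38 start and end. A change of the line in culture or a culture of another origin may account for the profile; neither was tested, since no reference library of colonic epithelial or mesothelial cells was analysed here.

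The lower interferon-stimulated genes with 2'-FL were weighed against technical explanations. With every library thinned to the smallest total, the median of the list stayed at -0.22 (standard error of the difference between library means 0.07). Totals lay between 19978583 and 25251187 and values are scaled to library size, so thinning could hardly move the median and is no test of depth. With each library's trend with GC content and length removed, the median was -0.20 (standard error 0.08), which argues against these trends as the whole cause. Genes listed for type I interferon were lower than those listed for interferon-gamma by a mean difference of -0.26 ± 0.07 (SE, n = 3 each), but both lists were written after interferon genes had been seen to be lower and 21 of 27 and 27 of 29 of their genes are in fixed lists, so this is no test. The 10 splits of the 6 libraries are too few for a share under 0.05: the real split gave a median of -0.22, a size reached by 1 of 10, itself, and the highest size of the other splits was 0.19. A lower response to the interferon-gamma in the medium, other differences between cultures, which are confounded with treatment here, and 2'-FL itself all stay open.

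The higher contractile genes were weighed in the same way. Smooth muscle cells in the culture would bring their abundant transcripts with Acta2. Tagln, Myh11, Actg2 and Des together gained 2.24 CPM where Acta2 gained 168 CPM. But Tagln, Myh11, Actg2 and Des were chosen after the data were seen and averaged at most 3.02 CPM, so their small gain is no test. In the same list, Cald1 averaged 1396 CPM in controls and 1559 CPM with 2'-FL. Myl9 averaged 7.63 and 12.8 CPM, and Cnn1 4.05 and 6.71 CPM, in the same order. With GC and length trends removed the median of the list was 0.65, against 0.64 before (standard error 0.14). The real split's median was reached by 1 of 10 splits, itself, with 0.40 as the highest of the other splits, and 10 splits are too few for a share under 0.05. A list of serum response factor and actin genes had a median log2 fold change of 0.25, with 22 of 23 tested members higher and 11 past adjusted over the list alone by edgeR, but it was written after such genes had been seen to be higher and 8 of its 24 genes are in a fixed list, so it is no test. A shift in the contractile programme of the cells or smooth muscle cells in the culture may account for the 0.64, with 2'-FL or differences between cultures both open.

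Other groupings of the same libraries gave calls of their own. By edgeR, the real split called 0 genes, as few as any, so all 10 splits gave as many. The split of 2'-FL replicates 2 and 3 with control replicate 1 against the rest called 32. Whether this reflects a structure of the samples beside the treatment or chance was not tested. At an unadjusted p under 0.05 the real split had 1116 genes, as many as were reached in 2 of 10 splits, itself included, and the highest other had 1272. With the preset correlation the real split passed 8 lists; 6 of 10 splits, itself included, passed as many, and the highest other passed 13. These 10 splits are too few for a share under 0.05.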
